A study of Macaca mulatta with 27 samples.

How the data were processed

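Total RNA from 27 samples of 10 rhesus macaque embryonic stem cell lines was labelled as biotinylated cRNA from 300 ng per sample and hybridised to Affymetrix rhesus arrays, per the labels' protocols. The deposited values are intensity values, 1 per probe set and array, produced with GCOS per the submitters' processing notes; its version and settings are not given in the sources used here. After leaving out 2% of values at each end, the mean deposited intensity was 500 on every array (500.035 to 500.041), so the values had already been scaled to a common trimmed mean. A second deposited table holds the same intensity values together with present, marginal and absent detection calls from the authors; 1 cell that is blank in the first table was filled from the second, and 0 other cells differed. Sex, sire and dam came from a deposited attributes table of 0 and 1 entries, matched to samples by name. All sample columns were used.

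The tables hold 52865 probe sets, of which 158 controls were set aside. Of the remaining 52707, 24956 carry 1 gene symbol in the platform annotation, 361 carry several and are not named here, and 27390 carry none and are given by their identifier. Symbols were updated through gene identifiers to the RefSeq gene table of the rhesus telomere-to-telomere assembly MMU8v2.0, in which 24629 probe sets matched; no coordinates are given, since the array was designed on an earlier sequence. Where a gene had several probe sets, the one with the highest mean over all arrays stood for the gene, and differing probe sets are named in the text.

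Values were analysed as log2(signal + 16) with no further normalization. A fold change on this scale understates changes of dim genes. A probe set was tested if its signal exceeded the array's own median on at least 3 arrays, which left 32856 probe sets and 11317 genes. Male and female lines, and the quadruplet and triplet families, were compared with limma 3.58.1 in R 4.3.3 on the mean of each line's arrays. Differences among lines were tested with limma's F test on the 27 arrays. All p-values over probe sets were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The share of variance between lines came from a one-way random effects decomposition. Distances between lines were 1 minus Pearson r of line means, and the mean distance of related pairs was compared with that of other pairs by permuting line names 100000 times (2-sided). Gene lists of at least 5 tested genes were tested with camera, with a preset correlation of 0.01 and again with an estimated one. Plots were drawn with matplotlib.

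The comparisons, gene lists, named genes rule and first set of alternatives were fixed before the data were examined. By that rule, up to 10 genes with the largest change in each direction were named for sex and family among those past the threshold with 1 symbol, 12 genes with the largest range of line means and 12 list members with the largest range for lines, up to 4 members of each list that was called, and POU5F1, NANOG, SOX2, DNMT3B and DPPA4 throughout. Probe sets of RERE, TBL1X, CLN3, IGFBP7, FZD3 and UGGT1, unnamed probe sets, X-linked list members and list markers described by level were chosen after their values were seen. The gene lists cover pluripotency, trophoblast, endoderm, mesoderm, neural ectoderm, fibroblast and matrix, blood and endothelium, Y-linked genes, X inactivation and escape, imprinting, MHC and antigen presentation, interferon response, metallothioneins and glutathione enzymes, immediate early and heat shock genes, p53 targets, the cell cycle, hypoxia and glycolysis, and FGF, TGF-beta and WNT signalling.

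Alternatives were other pseudocounts (1 and 64), no filter or a stricter one (75th percentile), quantile normalization or median centring, leaving out each line, fits on all arrays with the line as a random block, unmoderated or weighted fits, sex or family as a covariate, other distances, and other settings of the list test. Alternatives chosen after seeing the data were leaving out the 6 arrays with a GAPDH 3' to 5' ratio over 3, that ratio as a covariate, leaving out the 4 arrays with the highest median signal (alone and together with line 2906), a filter on present calls, distances over pairs of single arrays, and leaving out each array in turn for the F test. Where lines or arrays were left out, the probe sets tested stayed the same. The steps were tested on simulated data with the real means and spreads of all 32856 probe sets, with planted changes of 2 sizes at 100 probe sets each. For the F test the simulated lines differed only by the planted changes, so the real spread between lines was not part of it. A log2 change of 1 was recovered at 49% of 100 probe sets in the sex comparison and at 17% in the family comparison, and a change of 2 at 93% and 79%. A change of 1 in a single line was recovered at 16% and a change of 2 at 75% by the F test. False calls numbered 7, 4 and 9 among 32656 unchanged probe sets. These rates describe the simulated data and may not hold where whole arrays deviate from the others of their line.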

Results

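Gene expression was measured in 10 rhesus macaque embryonic stem cell lines, each grown from the inner cell mass of a separate blastocyst on mouse embryonic fibroblast feeders. RNA was taken from colonies picked by scraping and hybridised to 27 Affymetrix rhesus arrays. The deposited pedigree gives each line's sire and dam. Lines 106, 206 and 306 came from sire M106 and dam F244 (the triplet family). Lines 2706, 2906, 3006 and 3106 came from M106 and dam F88 (the quadruplet family). Line 2406 came from M106 and F77, line 3806 from M106 and F32, and line 906 from M36 and F183, so that 906 shared no parent with any other line. By the labels, 5 lines were male (106, 306, 906, 2706 and 3106, 15 arrays) and 5 were female (206, 2406, 2906, 3006 and 3806, 12 arrays). Line 2906 had 1 array, line 206 had 2, and the other lines had 3 each. The labels do not say that the arrays of a line came from separate cultures, so p-values among lines measure only the spread between these arrays, which may be technical. Sex and family were compared over line means, with the line as the replicate.

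Between 38.2% and 46.9% of probe sets were called present per array (median 43.8%), and the median signal ran from 94.1 to 159.7. Array 106c had both the lowest present share and the highest median. The ratio of 3' to 5' GAPDH signal, which rises as RNA degrades, was 13.3 on the single array of line 2906, 6.15 on 3006a, 4.61 on 106c, 3.41 on 3006c, 3.18 on 2406d and 3.04 on 2406e, and under 3 on the others. Arrays 106c, 206c, 906c and 306c had the 4 highest medians (159.7, 148.9, 137.5 and 137.4), so that each triplet line had 1 such array and the quadruplet lines had 0. Where a probe set was not called present in 1 group, its level there is background and limits the difference. The number of arrays limits the precision.

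POU5F1, the core transcription factor of pluripotent cells, averaged 14.38 ± 0.14 (log2 signal, SD over 10 lines), SOX2 13.99 ± 0.24 and the de novo DNA methyltransferase DNMT3B 13.65 ± 0.22. DPPA4 averaged 11.93 ± 0.26 and NANOG 8.98 ± 0.31. Of the 21 pluripotency genes on the array, 13 were called present on all 27 arrays and 1, DNMT3L, on none. LIN28A, TDGF1 and XIST were not analysed here. The median level lay at the 86.4th percentile of the arrays for pluripotency genes and at the 96.4th for 18 cell cycle genes. Such percentiles come from different probe sets, whose affinities differ, and do not rank expression between genes or lists.

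Among markers of differentiated cells, the median percentile was 50.1 for trophoblast genes, 56.6 for mesoderm, 57.3 for neural ectoderm, 63.5 for endoderm and 38.8 for blood and endothelium. ZIC2 at 14.19 ± 0.13 and HHEX at 13.68 ± 0.14 were called present on all 27 arrays, and CDX2, TBXT, NEUROG2 and PTPRC were called present on 0 arrays. Fibroblast and matrix genes stood at the 85.7th percentile, with VIM at 13.50 ± 0.49 and COL1A2 at 10.46 ± 1.17. In the other lists, interferon response genes stood at the 56.8th percentile, MHC and antigen presentation genes at the 73.6th, imprinted genes at the 75.0th, p53 targets at the 75.0th, signalling genes of the FGF, TGF-beta and WNT pathways at the 82.4th, immediate early and heat shock genes at the 83.0th, hypoxia and glycolysis genes at the 88.8th, and metallothioneins and glutathione enzymes at the 91.3th.

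The first comparison asked which genes differed among the 10 lines. Immediate early genes, which growth factors induce, were among those with the widest range between lines. EGR2 averaged 13.25 ± 0.27 in line 3106 and 12.29 ± 0.40 in 3006, against 7.98 ± 0.25 in 3806, and FOS averaged 12.68 ± 0.22 in 3106 against 8.01 ± 0.24 in 3806 (SD, n = 3 arrays each). EGR4 and PYROXD1 were likewise highest in 3006 and 3106, with EGR4 at 10.27 ± 0.30 and 10.76 ± 0.40 and PYROXD1 at 12.98 ± 0.62 and 12.49 ± 0.28. Of 11 immediate early and heat shock genes tested, 7 differed among lines. The arrays of 2406 differed widely from one another for these genes, with an SD of 2.93 for EGR2 and 4.18 for PYROXD1.

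Other genes marked single lines. SPMAP2 was at 11.03 ± 0.22 in line 3806 and at 4.82 ± 0.09 in 2406 (adjusted p = 2.89e-13), and HSBP1L1 ran from 4.80 ± 0.41 in 906 to 9.15 ± 0.35 in 306. Line 3006 had the highest metallothionein MT2A (14.62 ± 0.32), the highest KLF5 (11.93 ± 0.46), the highest PHLDA2, an imprinted growth regulator (12.36 ± 0.53), the highest ADM, a hypoxia-induced peptide (11.31 ± 0.37), and the highest SPRY4, a feedback inhibitor of FGF signalling (12.13 ± 0.43). The endoderm factor GATA6 was highest in 2406 (10.87 ± 1.24) and lowest in 106 (7.78 ± 0.29). LOC720650 ran from 4.43 ± 0.13 in 3106 to 9.22 ± 0.33 in 206. The type I collagen gene COL1A2 was between 11.22 and 12.25 in 106, 206, 306 and 906 and between 9.21 and 10.42 in the other lines. CCN2, a matrix-associated gene, was highest in 3006 (13.92 ± 0.31). Line 2906 was lowest for COL1A1 (5.29), KRT8 (5.56) and EIF5A (5.99) and highest for GATA3 (10.16) and IFIT3 (8.27), each on 1 array.

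**Figure D1:**
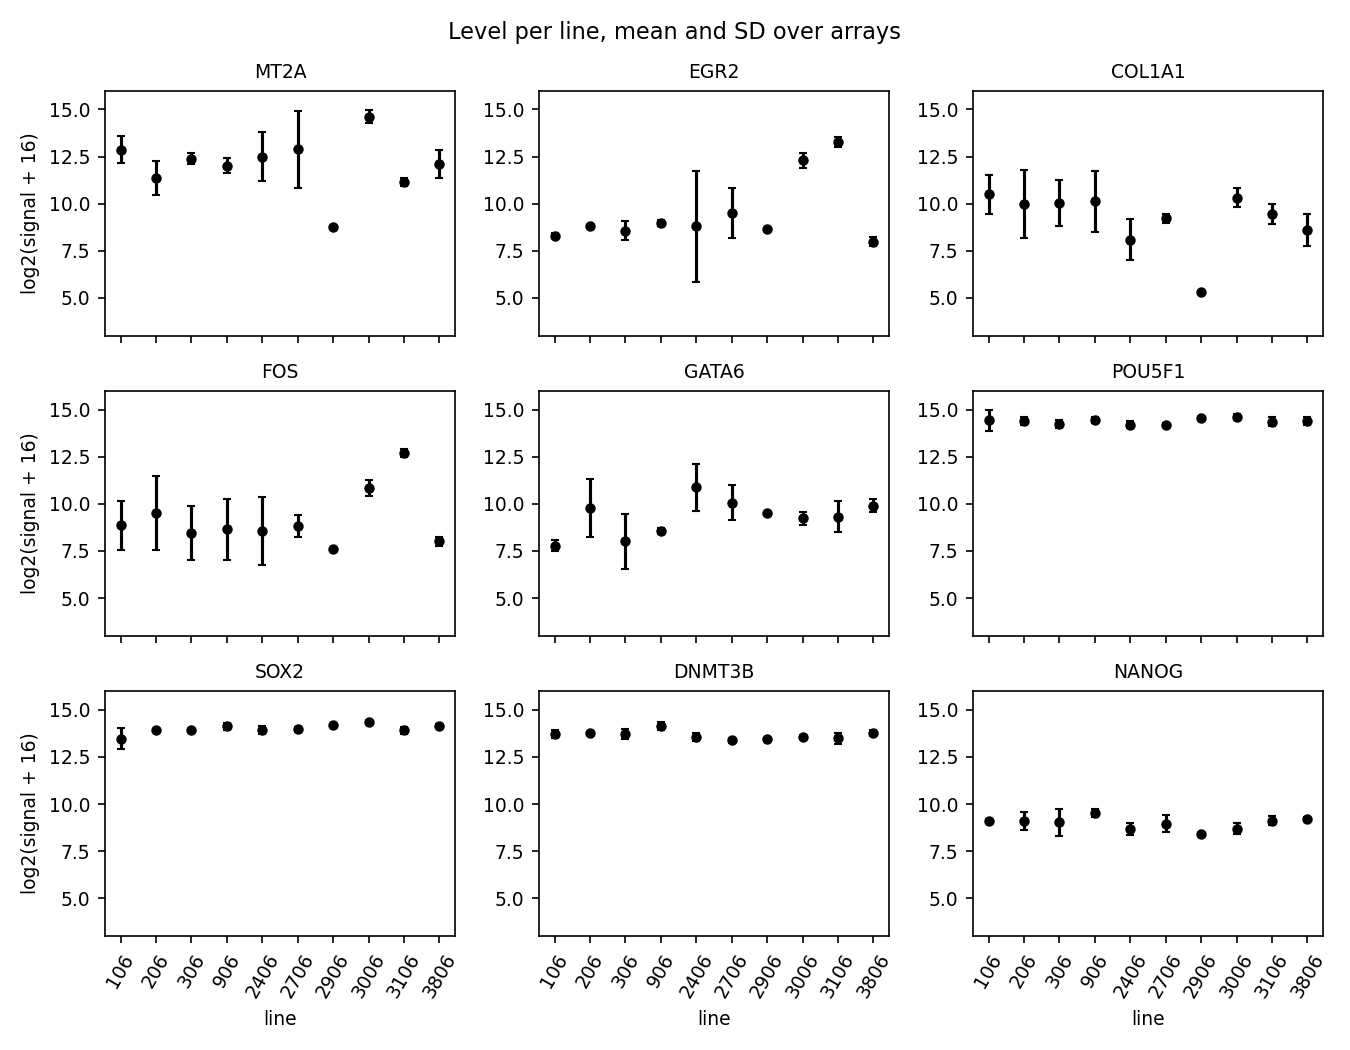
Level of 9 genes in the 10 lines, as log2(signal + 16); points are means and bars SDs over the arrays of a line (no bar for line 2906, with 1 array). POU5F1, SOX2, DNMT3B and NANOG stay within 1.11 of their lowest line, while EGR2 runs from 7.98 in line 3806 to 13.25 in line 3106.

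In all, 5460 of 32856 probe sets tested (16.6%) differed among lines in limma's F test at an adjusted p under 0.05, and 10682 had an unadjusted p under 0.05. They represented 1967 genes, and in 4707 of the 5460 the highest and lowest line means were over 1 log2 unit apart. POU5F1, SOX2, DNMT3B, DPPA4 and NANOG were not among them (adjusted p = 0.775, 0.115, 0.108, 0.108 and 0.333). Within the fixed lists, 7 of 20 pluripotency genes tested differed, 5 of 17 endoderm genes, 8 of 18 fibroblast and matrix genes, 11 of 27 signalling genes and 2 of 18 cell cycle genes. Line 2906 was the highest or lowest line in 50.6% of the 5460, and 2615 probe sets differed once the 6 arrays with a GAPDH ratio over 3 were left out. The count fell to 3449 without line 3006 and to 3334 with each array centred on its median. It was 3940 with the array letter as a block and 6331 without the 4 arrays of highest median signal.

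Differences among lines accounted for a median of 20.9% of a probe set's variance (interquartile range 0% to 42.5%), the rest lying between arrays of the same line. Immediate early and heat shock genes had a median share of 55.1%, hypoxia and glycolysis genes 51.2%, genes of the X inactivation list 50.3% and pluripotency genes 43.0%, against 19.9% for p53 targets and 20.1% for blood and endothelium. The median share was 11.8% with no filter on dim probe sets and 31.97% when only probe sets above the 75th percentile were kept, and 29.9% without the 4 arrays of highest median signal.

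The next comparison asked whether related lines had more similar profiles, a question the series title raises. The 3 triplet lines were close to one another, with a mean distance (1 minus Pearson r of line means) of 0.0224 ± 0.00235 (SD, 3 pairs), and the quadruplet lines 2706, 3006 and 3106 were at 0.0282 ± 0.00755 (3 pairs). Pairs sharing only the sire averaged 0.0333 ± 0.00619 (22 pairs without 2906) and pairs sharing no parent 0.0332 ± 0.00609 (8 pairs without 2906). Pairs with 2906 averaged 0.0733 ± 0.00861 (9 pairs). Line 2906 was nearest to 2406 (0.0551) and 3806 (0.0627), which share only its sire, and lay 0.0743 to 0.0785 from its 3 full siblings. A median of 80 probe sets differed between 2 triplet lines and 396 between 2 of those 3 quadruplet lines, against 541.5 for lines sharing only the sire and 807.5 for lines sharing no parent, always without 2906.

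Over all 10 lines, the 9 full-sibling pairs averaged 0.0425 ± 0.0262 and the other 36 pairs 0.0396 ± 0.016. The difference of 0.00288 was smaller than the spread (2-sided permutation test over 100000 draws of line names, p = 0.797). Without line 2906 it turned to -0.00794, full siblings then being closer (permutation p = 0.00243), and without the 4 arrays of highest median signal as well it was -0.00825 (permutation p = 0.00452). That closeness was not past the threshold when distances were averaged over pairs of single arrays instead of taken from line means (-0.00495 without 2906, permutation p = 0.162), nor without all 6 arrays of high GAPDH ratio, among them that of 2906 (-0.00745, permutation p = 0.132), nor over arrays of the same letter (-0.00742, permutation p = 0.212). The last of these keeps 2906, whose array shares its letter with no sibling. Line 2906 thus enters it only in pairs of non-siblings, which lowers the difference. Pairs sharing a parent differed from those sharing none by 0.00238 (permutation p = 1). The 9 pairs sharing none all involved line 906, so the permuted difference depends only on which line takes its place. With 10 lines this test could not have passed the threshold, and nothing is concluded from it.

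**Figure D2:**
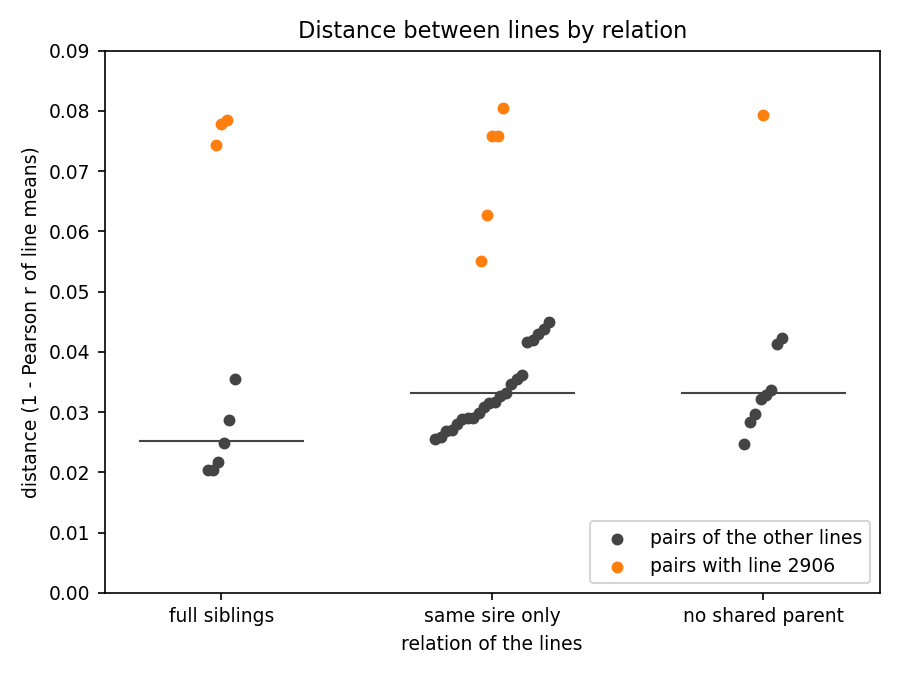
Distance between line means for each of the 45 pairs of lines, by relation; grey points are pairs without line 2906 with their mean as a line, orange points are pairs with it. Among the other 9 lines, full siblings have the lowest mean and overlap with the other pairs, and every pair with 2906 lies above 0.055.

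The quadruplet and triplet families share the sire and differ in the dam, and their comparison addresses what sets 1 family apart from the other. Type I collagen COL1A2 was lower in the quadruplet lines (9.79 ± 0.46, n = 4 lines) than in the triplet lines (11.91 ± 0.29, n = 3), a log2 difference of -2.12 ± 0.27 (SE, limma adjusted p = 0.045), and its other probe set differed by -2.02 ± 0.22. Also lower in the quadruplet lines were ZFTA (4.60 against 6.77, difference -2.17 ± 0.25) and TRABD2A (5.36 against 7.32, -1.96 ± 0.19). So were FOXN1, a thymic epithelial transcription factor (5.63 against 7.19, -1.57 ± 0.20), and NGB, neuroglobin (4.55 against 5.82, -1.27 ± 0.16). Higher in the quadruplet lines were OR10A6, an olfactory receptor gene (6.86 against 5.14, 1.72 ± 0.21), the transcriptional coactivator CITED1 (7.46 against 5.85, 1.61 ± 0.19) and GRINA (12.03 against 10.55, 1.49 ± 0.15). Apart from COL1A2 and GRINA, these levels lay near or under the middle of the arrays' signals, and their detection calls are not given here. With a filter on present calls, 1 probe set was called higher. NGB ran from 4.36 to 8.33 over single arrays (within-line SD 1.17), with 0% of its variance between lines, and without the 4 arrays of highest median signal its difference was -0.11 ± 0.16. Without those arrays CITED1 (1.06 ± 0.26, adjusted p = 0.213), OR10A6 (1.41 ± 0.32, 0.192), FOXN1 (-1.41 ± 0.21, 0.0851) and the first COL1A2 probe set (-2.05 ± 0.30, 0.0812) also lost the call. POU5F1 (0.07 ± 0.17), SOX2 (0.33 ± 0.19), DNMT3B (-0.26 ± 0.14), DPPA4 (-0.14 ± 0.23) and NANOG (-0.27 ± 0.19) did not pass, with adjusted p between 0.586 and 0.903.

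In all, 25 probe sets passed, 5 higher and 20 lower in the quadruplet lines, and 3139 had an unadjusted p under 0.05. Of these, 12 have no gene name here, and 8 genes passed by their brightest probe set. The largest differences were in unnamed probe sets, at -4.90 ± 0.21 (adjusted p = 0.000137) and, for MmuMitochon.6.1.S1_s_at, at -4.12 ± 0.23 (adjusted p = 0.000446). A CLN3 probe set differed by -2.87 ± 0.16, while the other 2 CLN3 probe sets differed by -0.34 at most. IGFBP7, FZD3 and UGGT1 passed in 1 probe set each (-1.51, -1.34 and -2.03), and their other probe sets differed by -0.62, -0.02 and -0.51 at most. Without the 4 arrays of highest median signal IGFBP7 differed by -0.23 ± 0.26. The count was 9, 4 and 4 without lines 106, 206 and 306, 7, 55, 10 and 13 without lines 2706, 2906, 3006 and 3106, and 9 with sex as a covariate. It was 20 without the arrays of high GAPDH ratio, with 11 of the 25 among them, and 18 without the 4 arrays of highest median signal, with 13 of the 25 among them. Without moderation of the variance the count was 3, with the 75th percentile filter 10, and with the filter on present calls 11, 1 of them higher.

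**Figure D3:**
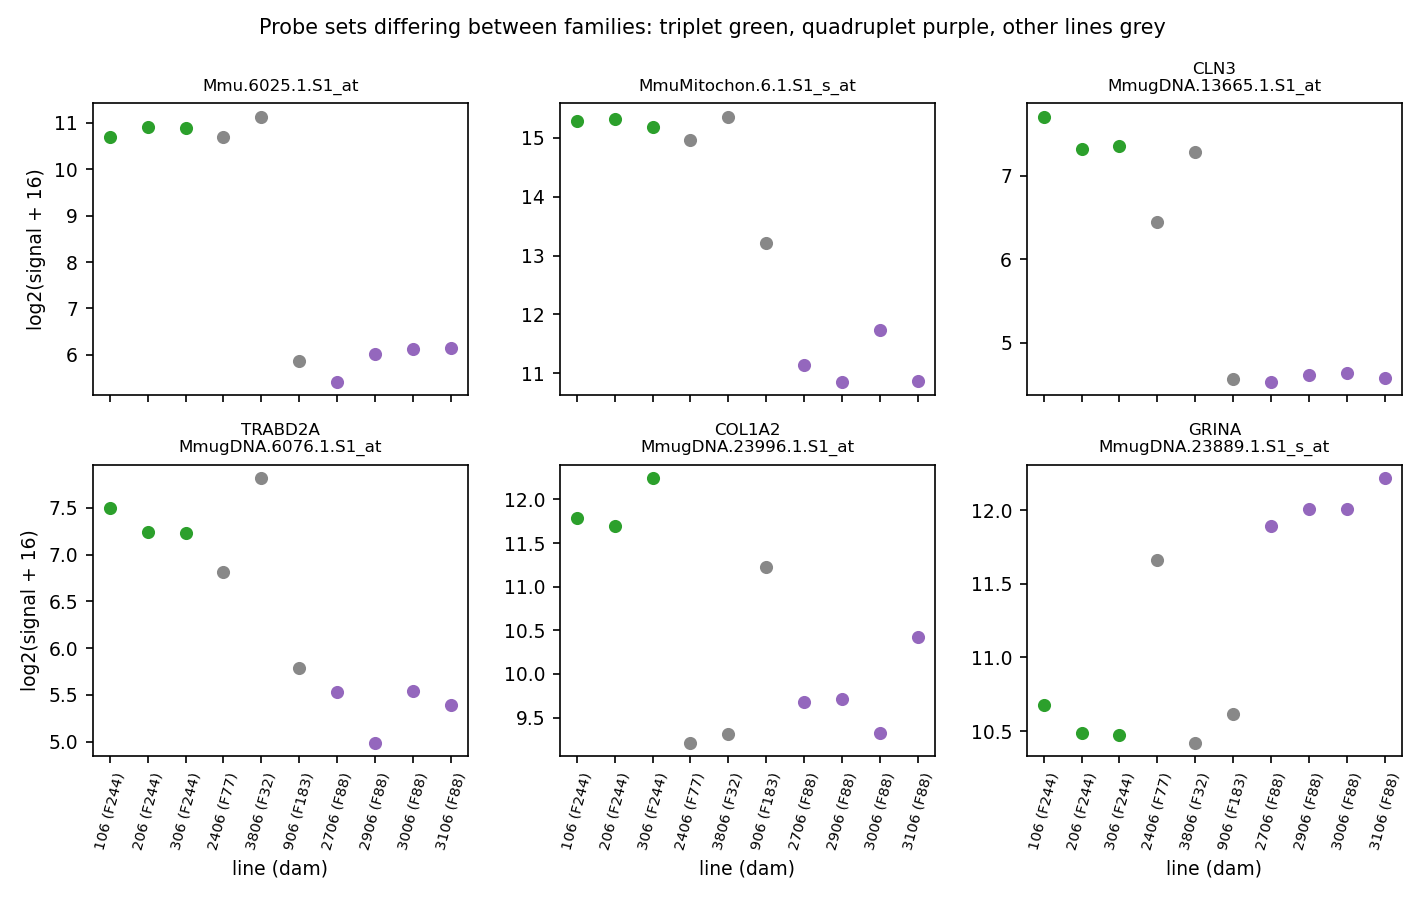
Level of 6 probe sets in the 10 lines, as log2(signal + 16) means over arrays, with lines ordered by dam (triplet green, quadruplet purple, others grey). The unnamed probe set of the first panel lies at 10.68 or above in 5 lines and at 6.14 or below in the quadruplet lines and 906, and COL1A2 is high in the triplet lines and 906.

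None of the 17 gene lists tested shifted between the families (camera in limma with a preset correlation of 0.01; 4 lists had an unadjusted p under 0.05, and 0 passed with an estimated correlation). The lowest adjusted p, 0.0874, was shared by 4 lists: fibroblast and matrix genes (12 of 18 lower in the quadruplet lines, median -0.25, with COL1A2 past the threshold alone), endoderm genes (11 of 17 higher, median 0.25), immediate early and heat shock genes (9 of 11 higher, median 0.42) and hypoxia and glycolysis genes (10 of 12 higher, median 0.22). With an estimated correlation each was at adjusted p = 0.925. Adjusted over the list alone, 1 hypoxia and glycolysis gene was higher, and 1 gene each of the pluripotency, neural ectoderm and fibroblast lists was lower. The fibroblast list passed without line 2706 (adjusted p = 0.0472) and without 3006 (0.0171), with the 75th percentile filter (0.041), quantile normalization (0.0391) and averaged probe sets (0.000278), the hypoxia and glycolysis list without 2706 (0.0472), the endoderm list without 206 (0.000194) and without the 4 arrays of highest median signal (0.0239), and the immediate early list without 2706 (0.0472), without 2906 (0.0049) and without the arrays of high GAPDH ratio (0.00571). Without those arrays the mean of the fibroblast list was 0.0038 instead of -0.32, and without the 4 arrays of highest median signal it was -0.081 (adjusted p = 0.529).

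Male and female lines differed at few probe sets, some of them called present in a single sex only. A probe set with no gene name here stood at 14.49 ± 0.18 in the 5 male lines and 5.41 ± 0.77 in the 5 female lines, a log2 difference of 9.07 ± 0.30 (SE, limma adjusted p = 4.58e-09). MmugDNA.20222.1.S1_s_at, also unnamed, differed by -8.51, being called present on 12 of 12 female and 0 of 15 male arrays, so that its level in males is background and the size is a lower limit. A probe set annotated to RERE, a nuclear receptor corepressor gene on an autosome, was 6.39 ± 0.13 higher in male lines, and a probe set of TBL1X, an X-linked gene, was 1.86 ± 0.17 higher. The other 3 RERE probe sets differed by between -0.05 and 0.09, and the other 3 TBL1X probe sets by -0.78, -0.08 and 1.02, with an adjusted p of 0.591 or above. LRRC63 was the only gene to pass by its brightest probe set, at -0.82 ± 0.12 (adjusted p = 0.0275); its difference kept its sign and lost the call without any one of 9 of the 10 lines.

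**Figure D4:**
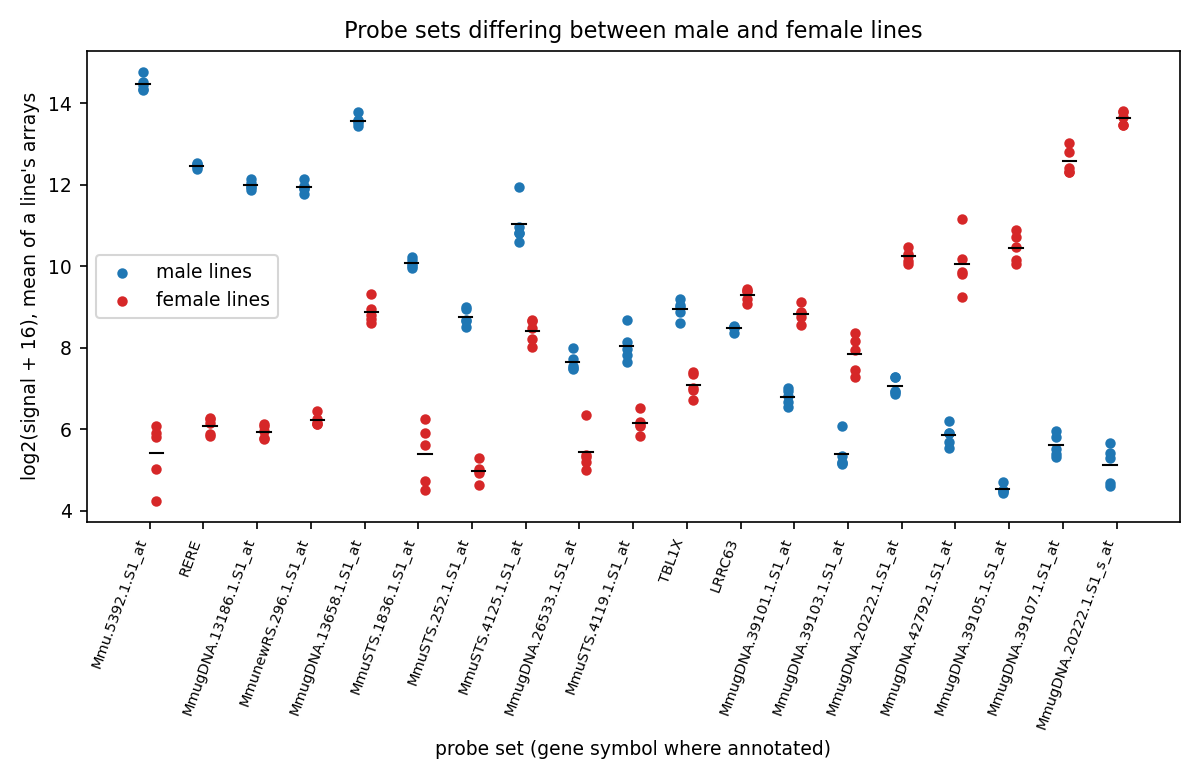
Level of the 19 probe sets that differed between male and female lines, as log2(signal + 16); each point is the mean of a line's arrays and bars are group means. The 5 male and 5 female lines do not overlap at any of them.

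In all, 19 probe sets passed, 11 higher and 8 lower in male lines, 16 of them unnamed here, and 1982 had an unadjusted p under 0.05. The median difference over 437 X-linked genes was -0.002, with 50.6% lower in male lines, and over 10729 autosomal genes -0.01, with 52.3% lower. POU5F1 (-0.10 ± 0.13), SOX2 (-0.23 ± 0.15), DNMT3B (0.06 ± 0.16), DPPA4 (-0.14 ± 0.17) and NANOG (0.32 ± 0.18) did not pass (adjusted p between 0.774 and 0.937), and POU5F1 was level with quantile normalization (0.0016). SRY was the only gene of the Y-linked list tested, at 7.71 ± 0.18 in male and 7.38 ± 0.49 in female lines (difference 0.33 ± 0.22, limma adjusted p = 0.781). This probe set did not separate the sexes, so its level cannot be read as SRY expression in either sex.

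Of the 17 gene lists, endoderm genes were called lower in male lines (median -0.23, adjusted p = 0.0393), but not with an estimated correlation (adjusted p = 0.799). Of 17 members, 13 were lower and 0 passed alone: GATA6 differed by -1.11 ± 0.42, FOXA2 by -0.90 ± 0.25, FOXA1 by -0.82 ± 0.34 and GSC by -0.80 ± 0.37, all transcription factors of early endoderm or the organiser. The call ended under 5 of the processing alternatives and without lines 106, 206, 306, 2406 or 3806, the adjusted p without 1 of these reaching 0.158, and it was 0.0981 without the 4 arrays of highest median signal. The adjusted p was 5.52e-05 without the arrays of high GAPDH ratio.

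Genes known to escape X inactivation in humans were lower in male lines in 9 of 15 cases (median -0.11), and the list did not pass (adjusted p = 0.066; 0.799 with an estimated correlation). Adjusted over the list alone, 3 members were lower in males, and over all probe sets 0 were. The histone demethylase KDM5C differed by -0.70 ± 0.17, the zinc finger gene ZFX by -0.70 ± 0.18 and OFD1 by -0.64 ± 0.17. The list passed without line 2906 (adjusted p = 2.68e-05), without line 906 (0.0278), without the arrays of high GAPDH ratio (2.63e-08), and with all probe sets of a gene averaged (0.00349).

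No other list passed under the settings chosen beforehand as the primary ones. The adjusted p was 0.0751 for p53 targets (11 of 14 higher in male lines), 0.236 for fibroblast and matrix genes (12 of 18 higher), 0.25 for immediate early and heat shock genes (8 of 11 higher) and 0.393 or above for the rest. Without line 3006, p53 targets (0.00224), immediate early genes (0.0123) and fibroblast genes (0.0309) also passed, and without line 906 p53 targets did (0.0278). Fibroblast genes passed with all probe sets of a gene averaged (0.00744), and signalling genes, lower in male lines, without the arrays of high GAPDH ratio (0.012). All these calls rest on the preset correlation; with an estimated one, run on all lines, 0 lists of the sexes passed. Of the 4 arrays of highest median signal, 3 came from male lines, and p53 targets and fibroblast genes were higher there than on the line's other arrays: p53 targets averaged 1.10 on 106c against -0.04 and 0.03, and fibroblast genes 0.78 against 0.03 and -0.05 (log2, relative to the mean array). Without the 4 arrays the adjusted p was 0.343 for p53 targets and 0.364 for fibroblast and for immediate early genes.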

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

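Adjusting the family differences for RNA integrity, leaving out arrays, the separate test of NGB and IGFBP7, comparing the probe sets of 1 gene, and the tests of the RERE and TBL1X probe sets were chosen after the result was seen, and the other tests of this part before it. Values of single lines named here lay far from the other lines of their group by Dixon's test, which 15 of 112 groups exceeded; the chance rate of about 1 in 20 holds for groups not picked by their values, and some of these genes were named for their range over lines, so the count is not set against it. A dependence of the sex difference on the family was called at 0 of the 19 probe sets that differed by sex and at 0 of all probe sets tested (limma; 1285 with an unadjusted p under 0.05).

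The probe sets that differed between the families call for the first weighing. Of the 35 splits of the 7 lines into 4 and 3, only the real 1 gave as many as 25 probe sets, and the highest other, the split of these lines by sex, gave 18. With so few splits this is weak evidence against a random grouping of these lines. It cannot exclude differences that any 2 sets of siblings might show by chance. RNA integrity, as the GAPDH ratio measures it, is argued against as the whole cause, since 24 of the 25 kept their call with that ratio as a covariate. Without the 6 arrays of high ratio, which leaves 6 of the 7 lines, only 11 did, for a cause that was not tested. A median of 0.939 of the difference was then left (interquartile range 0.883 to 1.02), with SEs at a median of 1.10 times the former. The actin ratio was not tried. The arrays of highest median signal, 1 in each triplet line, are argued against as the whole cause too. Without the 4 arrays of highest median signal a median of 0.915 (0.840 to 0.956) and 13 calls were left. These arrays may account for NGB and IGFBP7, of which 0.149 or less was left (-1.27 ± 0.16 became -0.11 ± 0.16, and -1.51 ± 0.15 became -0.23 ± 0.26). They may also account for part of CITED1 (1.61 ± 0.19 became 1.06 ± 0.26). A batch that took in all arrays of a family would remain after this step. Such a batch cannot be told apart from the family and was not tested. Feeder or fibroblast cells are argued against only as far as the fibroblast genes track them. Adjusting for their mean left a median of 0.992 over 22 probe sets. The 16 fibroblast genes other than COL1A2 and IGFBP7 differed by a mean of -0.24 ± 0.16 (SE over genes, not lines, 11 lower) against -1.88 for the called probe sets of these 2. The list mean also followed single arrays, at 0.78 on 106c against 0.03 and -0.05 on its line mates. The family shift of the list was 0.0038 without the arrays of high GAPDH ratio and -0.55 with averaged probe sets, so such cells cannot be excluded. In 4 of 5 genes with another tested probe set (CLN3, IGFBP7, FZD3 and UGGT1, but not COL1A2) no other probe set differed by 0.5 of the called difference. The called probe set was picked for its difference, so smaller values in the others follow in part from that choice. A sequence difference inherited from the dams under single probe sets is thus not singled out, and remains possible and untested, IGFBP7 aside. COL1A2 was lower in both of its probe sets but did not follow the families alone. Line 906, which shares no parent with the triplet lines, was at 11.22 and 10.25. Lines 2406 and 3806 were at 9.21 and 9.32 in the first probe set. For COL1A2 a difference between the dams, between cultures or between batches of arrays remains open and untested.

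Line 2906 was far from every other line, with a mean distance of 0.0733 where the next line had 0.0445. It was lowest for COL1A1 (5.29) and KRT8 (5.56) and highest for the trophoblast factor GATA3 (10.16). A single array with nothing to average over may be part of the cause, since array 106c was farther from the arrays of other lines (0.107) than the 2906 array (0.0878). RNA degradation cannot be told apart from a difference of the line itself. Over 26 arrays of other lines, those with a higher GAPDH ratio than their line mates deviated somewhat in the direction of 2906. Spearman rho was 0.309 (permutation p = 0.124) and Pearson r 0.435 (permutation p = 0.027), and r was 0.378 without the 2 farthest arrays. Each array was set against its own line mates, so deviations within a line depend on one another. The permutation took the arrays as independent, so nothing is concluded from its p-values. Line 2906 has no second array that would separate degradation from a difference of the line, and its closeness to its siblings stays undetermined.

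The RERE and TBL1X probe sets that were higher in male lines were weighed as well. RNA integrity, as the GAPDH ratio measures it, is argued against as the whole cause, since 2 of 2 kept their call with that ratio as a covariate. A change of the whole RERE transcript is argued against too, as none of its other 3 probe sets differed by more than 0.094 against 6.39. For TBL1X this cannot be told apart, because 1 of its other 3 probe sets differed by 1.02, another by -0.08 and the brightest by -0.78. Both probe sets may instead detect a related sequence carried by males only, such as a Y-linked copy, which was not tested because no probe sequences were used here.

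Of 100 splits of the 10 lines into 5 and 5, 2 gave as many probe sets as the 19 of the sexes, 1 of them the real split. A count this high is thus rare but not particular to sex. The other split gave more, 28, and set lines 106, 206, 306, 2406 and 3806 against the quadruplet lines and 906. That split holds the family contrast, from which the 12 probe sets it shares with the families follow. Its other calls were not accounted for, and it shared 0 probe sets with the sexes. For the 10 lines, 1 of 100 regroupings of the arrays, the real 1, gave as many as 5460 probe sets (highest other 11). Arrays of a line were thus more alike than arrays grouped at random. They may be repeats of 1 culture, so chance differences between cultures are not excluded by this. For the gene list of the sexes a random grouping cannot be excluded, as 69 of 100 splits called as many as that 1 (highest other 7). For the families 0 lists were called, a count that every split reaches (35 of 35, highest other 4), so this comparison says nothing of them.

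The pluripotency factor NANOG was highest among male lines in 906 (9.53), SOX2 was lowest of the 10 lines in 106 (13.46), and DNMT3B was highest of them in 906 (14.15). ADM, induced by hypoxia, was highest in 3006 (11.31). FOXA1, an endoderm factor, was higher in 3806 (7.73) than in the other female lines. LRRC63 was lower in 106 (8.36) than in the other male lines. Among unnamed probe sets that differed by sex, MmugDNA.26533.1.S1_at was highest of the female lines in 2406 (6.35), and among the male lines MmugDNA.39103.1.S1_at was highest in 906 (6.08), MmugDNA.39105.1.S1_at in 106 (4.71) and MmuSTS.4125.1.S1_at in 906 (11.96). The first was called present on 0 of 12 female arrays, and MmugDNA.39103.1.S1_at and MmugDNA.39105.1.S1_at on 0 of 15 male arrays, so these values are background. An unnamed probe set that differed between the families was lowest of the quadruplet lines in 2706 (11.05).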

How the results depend on the processing

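Leaving out arrays with a high GAPDH ratio, that ratio as a covariate, leaving out the 4 arrays of highest median signal (106c, 206c, 306c and 906c), the filter on present calls, distances over pairs of arrays and leaving out single arrays were chosen after the data were seen. The 19 probe sets of the sexes ranged from 16 to 21 in all alternatives but 2, with 45 when all arrays were fitted with the line as a random block and 34 with the array letter added; deviations of arrays from their line correlated over 0.1 in 30 of 77 pairs of the same letter and 47 of 223 of other letters, so the letters pair the arrays in part. The 25 of the families became 350 and 342 under these, 14 with no filter, 10 with the 75th percentile, 11 with the filter on present calls, 3 without moderation, 54 with weights, 9 with sex as a covariate, and 4 to 55 without single lines; 20 were called without the arrays of high GAPDH ratio (11 of the 25 among them) and 18 without the 4 arrays (13 of the 25 among them). The 5460 among lines became 3334 with median centring, 2615 without the arrays of high GAPDH ratio, 2194 at an adjusted p under 0.01, 3940 with the letter as a block, 6331 without the 4 arrays, and 3449 to 7317 without single lines or arrays. The share of variance, 20.9%, was 11.8% with no filter, 31.97% with the 75th percentile, 16.7% with median centring, 18.1% without the arrays of high GAPDH ratio, 29.9% without the 4 arrays, and 16.7% to 26.2% without single lines. The difference between full siblings and other pairs, 0.00288, was -0.00745 without the arrays of high GAPDH ratio (permutation p = 0.132), -0.00742 over arrays of the same letter (0.212, with 2906 only in pairs of non-siblings), -0.00495 over array pairs without 2906 (0.162), -0.00825 without the 4 arrays and 2906, and -0.00794 to 0.00868 without single lines. That between pairs with and without a shared parent was -0.00161 to 0.00409 without single lines, and without 906 it has no value. The 1 list of the sexes became 0 with log2(signal + 64), no filter, the 75th percentile, quantile normalization, median centring, an estimated correlation and without the 4 arrays, 3 without the arrays of high GAPDH ratio and with all probe sets of a gene averaged, and 0 to 4 without single lines. The 0 lists of the families became 1 with the 75th percentile, quantile normalization, averaged probe sets, without the arrays of high GAPDH ratio and without the 4 arrays, and 0 to 3 without single lines. Stricter filters tested fewer probe sets, the random block counts arrays as replicates, and for the other changes the cause was not tested. In all, 82 values changed sign, 80 of them called neither before nor after. By sex, the mean of the mesoderm list was -0.0044 with log2(signal + 1), -0.049 with the 75th percentile, -0.0089 with quantile normalization, -0.016 with median centring, -0.14 without the arrays of high GAPDH ratio, -0.055 without the 4 arrays and -0.052 to 0.087 without single lines. The cell cycle list was 0.0091 with log2(signal + 64), 0.040 with the 75th percentile, 0.0073 with quantile normalization, 0.015 without those arrays, 0.044 with averaged probe sets and -0.029 to 0.020 without single lines. With the 75th percentile the neural ectoderm list was 0.032 and the interferon list 0.039, and the hypoxia list was -0.0033 with median centring and -0.0020 without the 4 arrays. Without the arrays of high GAPDH ratio the trophoblast list was 0.098, the imprinted list 0.013 and the immediate early list -0.17, and with averaged probe sets the trophoblast list was 0.031, the blood list 0.038 and the imprinted list 0.020. Without single lines, lists ran from -0.19 to 0.17 (trophoblast), -0.097 to 0.015 (neural ectoderm), -0.068 to 0.027 (imprinted), -0.044 to 0.11 (hypoxia) and -0.036 to 0.51 (immediate early). POU5F1 was 0.0016 with quantile normalization, and DNMT3B -0.0056 with the GAPDH ratio as a covariate, -0.076 with family as a block and -0.056 to 0.14 without single lines. By family, the mesoderm list was -0.014 with no filter, and the MHC list 0.0081 with quantile normalization, 0.046 with median centring, 0.0067 without the arrays of high GAPDH ratio, 0.053 with averaged probe sets and -0.10 to 0.042 without single lines. Without those arrays the trophoblast list was -0.062, the fibroblast list 0.0038, the X inactivation list 0.041 and the p53 list 0.21, and with averaged probe sets the X inactivation list was 0.0057. Without the 4 arrays the neural ectoderm list was 0.10, the blood list 0.0060, the MHC list 0.069 and the p53 list 0.18. Without single lines, lists ran from -0.093 to 0.35 (trophoblast), -0.17 to 0.051 (X inactivation), -0.20 to 0.065 (p53 targets), -0.10 to 0.18 (metallothioneins) and -0.037 to 0.11 (signalling). Other values for single genes, probe sets and lists kept their sign: 415 family values stayed on their side of the threshold and 219 lost the call, 703 and 16 by sex, 1120 and 77 for line genes with 1 gained, and 520 and 12 for lists with 21 gained. The second deposited table holds the same values and was not run. Signal over background was judged by the detection calls alone, with 38.2% to 46.9% present per array.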

Other observations

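These values were chosen after they were seen, and none comes from a test of an explanation. Spread between arrays of the same line was widest for trophoblast genes (median SD 0.57, 7 genes), endoderm genes (0.45) and immediate early and heat shock genes (0.45), and narrowest for hypoxia and glycolysis genes (0.25), against 0.29 over all 11317 genes. The calcium-binding protein gene S100A6 ran from 8.24 to 15.19 over single arrays (within-line SD 2.12), INHBA, an activin subunit, from 4.97 to 10.46, and JUND, an AP-1 subunit, from 4.86 to 9.76, with 0% of the variance of each between lines.

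Of the 25 probe sets that differed between the families, 2406 lay nearer the triplet lines at 18, 3806 at 18, and 906 nearer the quadruplet lines at 15, and 11 had all 3 lines that way. Of the 6 probe sets whose identifier holds the word Mitochon, 2 were past the threshold, both lower in the quadruplet lines, 2 others were lower without passing (-2.80, adjusted p = 0.112, and -1.21, adjusted p = 0.404), and 2 were higher by 0.26 and 0.27. The first 2 principal components of the 27 arrays held 15.6% and 11.1% of the variance, and arrays 106c, 206c, 906c and 306c scored highest on the first (111, 61.8, 50.1 and 33.8).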
